A study of Mus musculus with 2 samples.

How the data were processed

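The study measured single-cell RNA from CD45-positive cells sorted out of subcutaneous tumours grown from MOC2, a mouse oral carcinoma line, in female C57BL/6 mice aged 6 to 7 weeks. Mice received vehicle or Momordicine-I, a triterpenoid from bitter melon, at 30 mg/kg by daily intraperitoneal injection. Each arm had 10 mice, and the tumours of 3 mice per group were pooled before sorting with a CD45-FITC antibody and propidium iodide, so each group is 1 library and the series has no replicates.

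The authors deposited raw UMI counts per gene and barcode for each library, with 32285 genes. Libraries were made with 10x Genomics 3' v3.1 chemistry per the labels' protocols, and Cell Ranger 6.0.2 with the mm10 genome is named in the submitters' processing notes. The deposited counts held 3642 barcodes and 33998491 UMIs in the vehicle library and 4693 barcodes and 41804810 UMIs in the Momordicine-I library, with medians of 5502.5 and 4845 UMIs per barcode. Gene positions come from the GENCODE annotation of GRCm38 (mm10), matched by Ensembl identifier, and all 272 named genes had a position.

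Cells with fewer than 200 detected genes (25 vehicle and 26 Momordicine-I barcodes) or more than 10% mitochondrial UMIs (274 and 322) were removed, which left 3364 and 4370. Scrublet's automatic threshold marked 2 and 1 of these as doublets. By a rule fixed for that case, the highest scoring cells at 0.8% per 1000 barcodes were removed instead, 91 and 153, leaving 3273 and 4217 cells. Both libraries were clustered together with scanpy 1.11.5 in Python 3.11.15 (2000 variable genes without immunoglobulin and T cell receptor segments, 30 principal components, 15 neighbours, Leiden resolution 1), which gave 27 clusters. Clusters were named "X-like" from 24 marker lists. A cluster stayed unnamed where its leading genes went against its name, where fewer than 3 markers were detected, or where its median UMI count was low and no marker led it.

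The comparisons, filters, markers, 33 gene lists, the rule for named genes and 14 alternatives were chosen before the data were examined. Some choices came later. The guards on cluster names were revised once after the first names were seen. Clusters with a median above 2% neutrophil-marker UMIs were set apart as mixed after the clusters were seen, which kept the only cluster led by macrophage markers out of its class. Gene expression planned for macrophage-like cells was therefore measured in mononuclear phagocytes, the monocyte-like cluster and the mixed neutrophil and macrophage-like cluster together, limited to cells with at most 0.580% neutrophil-marker UMIs, the 99th percentile in B-like cells. This gate is a range and not a type: 31 of 278 vehicle and 69 of 415 Momordicine-I phagocytes lay within 2-fold of it, and over the gated cells the median share of marker UMIs was 0 in both libraries for T cell, Treg, NK, B cell and mature dendritic markers, 0.0315% and 0.0221% for cDC1, 0.00882% and 0.00982% for ILC2 and 0.00488% and 0% for cDC2 markers. Over the summed UMIs of the gated cells, on which genes were compared, T cell markers made up 0.0313% in the vehicle and 0.00719% in the Momordicine-I library. B cell markers made up 0.00104% and 0.00114%. The naive T-like, Treg-like and gamma-delta-like clusters, the mixed cluster, 5 alternatives and the interferon values by neutrophil-like cluster were added after the data were seen.

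For each class with at least 50 cells and 100000 UMIs in both libraries, UMIs were summed per library and given as CPM of that sum, with the ratio of Momordicine-I to vehicle. Shares have exact Clopper-Pearson 95% intervals and ratios exact conditional binomial 95% intervals, which cover counting error only. For CPM ratios the unit counted is the UMI. UMIs of the same cell are taken as independent, so these intervals leave out variation between cells. The interval of a list median comes from the spread of its members' log2 ratios. With 1 library per group no test was run and no p-value is given. A gene at 0 UMIs is compared against a floor of 3 counts. Genes were named by size: among those with at least 50 CPM in 1 or both libraries and at least 50 UMIs, without immunoglobulin and T cell receptor segments and mitochondrial, ribosomal protein, haemoglobin and predicted genes, the genes whose ratio interval lay farthest from 1, taking 12 higher and 12 lower in gated phagocytes in place of macrophage-like cells, 8 and 8 in neutrophil-like, B-like and T-like cells and 5 and 5 elsewhere. Up to 4 members per described list and a fixed set per class were added. A list member was measured with at least 20 UMIs and counted as higher or lower at a ratio of 1.5 or its inverse. Each list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression in 10 bins, as a description of these libraries. Of 357 list and class pairs computed, 98 lay below and 47 above the central 95% of random lists. The 60 pairs described, of which 33 lay below and 7 above, were picked after the values were seen.

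The ratio intervals and list percentiles were tested on simulated counts. These were Poisson draws per library from a pooled profile, the model that the intervals assume, so the rates for unchanged genes follow from that model. Cells, clustering, gating and differences between mice were not simulated. The rates below therefore do not carry over to genes whose UMIs lie in few cells. In gated phagocytes, 4.74% of unchanged genes among 6447 had an interval that left out 1, and 84% and 96% of genes changed to a ratio of 0.5 and 2 were recovered. The corresponding values were 4.70%, 96% and 98% over 9070 genes in neutrophil-like cells and 4.92%, 66% and 90% over 4424 genes in B-like cells. Where cells were thinned to 2000 UMIs, those with fewer were left out. Alternatives changed the filters, doublet removal, clustering, scaling (including edgeR 4.0.16 TMM factors in R 4.3.3), depth and list minimums. Another scaling moved log2 ratios by more than 0.1 in neutrophil-like cells and gated phagocytes. The amount subtracted was 0.16 by median-of-ratios factors and 0.13 by TMM in neutrophil-like cells, which lowered their ratios. In gated phagocytes it was -0.12 by TMM, which raised them. Tumour-like cells, with 27 and 56 cells, were below the minimum for gene comparisons.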

Results

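Immune cells sorted on CD45 from MOC2 oral carcinomas were profiled after daily vehicle or Momordicine-I, a bitter melon triterpenoid. The series title places the question in tumour-infiltrating macrophages and B lymphocytes. After filtering, the vehicle library held 3273 cells with 31450667 UMIs and a median of 5681 UMIs per cell, and the Momordicine-I library held 4217 cells with 38097546 UMIs and a median of 4937. Each library pooled the tumours of 3 mice. There was 1 library per group and thus no replicate, so the values below compare these libraries. Every interval of a share or ratio covers counting error only.

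B-like cells, led by Cd79a, Ebf1 and Ms4a1, made up 6.78% of vehicle cells (222 cells, exact 95% interval 5.94 to 7.70%) and 2.18% of Momordicine-I cells (92 cells, 1.76 to 2.67%), a ratio of 0.322 (0.249 to 0.412). A naive T-like cluster led by Lef1 and Tcf7, transcription factors of naive T cells, was lower to a similar degree, at 4.89% and 1.42% (ratio 0.291, 0.213 to 0.394). Gamma-delta-like T cells, led by the cytokine gene Il17a, went the other way, from 1.65% (54 cells) to 4.06% (171 cells), a ratio of 2.46 (1.80 to 3.40). These 2 ratios were 0.514 for naive T-like cells with each library clustered on its own and 1.43 for gamma-delta-like cells at Leiden resolution 0.5. NK-like cells were at 3.09% and 3.06% (ratio 0.991, 0.758 to 1.30, and 0.955 to 1.14 over the alternatives).

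Neutrophil-like cells were the most numerous class, at 55.2% of vehicle and 58.4% of Momordicine-I cells (ratio 1.06, 0.995 to 1.12). Treg-like cells were at 3.21% and 2.02% (ratio 0.628, 0.466 to 0.844), group 2 innate lymphoid (ILC2-like) cells at 1.96% and 1.04% (ratio 0.534) and basophil-like cells at 1.99% and 1.09% (ratio 0.549). Mononuclear phagocytes were at 8.49% and 9.84% (ratio 1.16, 0.993 to 1.35). Within them the monocyte-like cluster was at 5.32% and 7.11% and the mixed neutrophil and macrophage-like cluster at 3.18% and 2.73%. Gated phagocytes, those low in neutrophil RNA, were at 2.69% and 4.08% (ratio 1.52, 1.17 to 1.98). Dendritic-like cells were at 3.54% and 4.36% (ratio 1.23, 0.971 to 1.57, and 0.997 with each cell classed by its own score). Over cells of immune classes alone the B-like ratio was 0.333 and the gamma-delta-like ratio 2.54. Over immune cells outside the neutrophil-like class the ratios were 0.390 for B-like, 0.353 for naive T-like, 2.98 for gamma-delta-like, 1.20 (0.918 to 1.57) for NK-like, 0.761 (0.565 to 1.02) for Treg-like, 1.49 (1.18 to 1.90) for dendritic-like and 1.84 (1.41 to 2.40) for gated phagocytes. Unnamed clusters held 4.74% and 5.03% of cells, and a low-UMI tumour-like cluster 3.24% and 5.12%, numbers that the CD45 sort can set. A mixed neutrophil and fibroblast-like cluster held 0.367% and 0.711%.

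**Figure D1:**
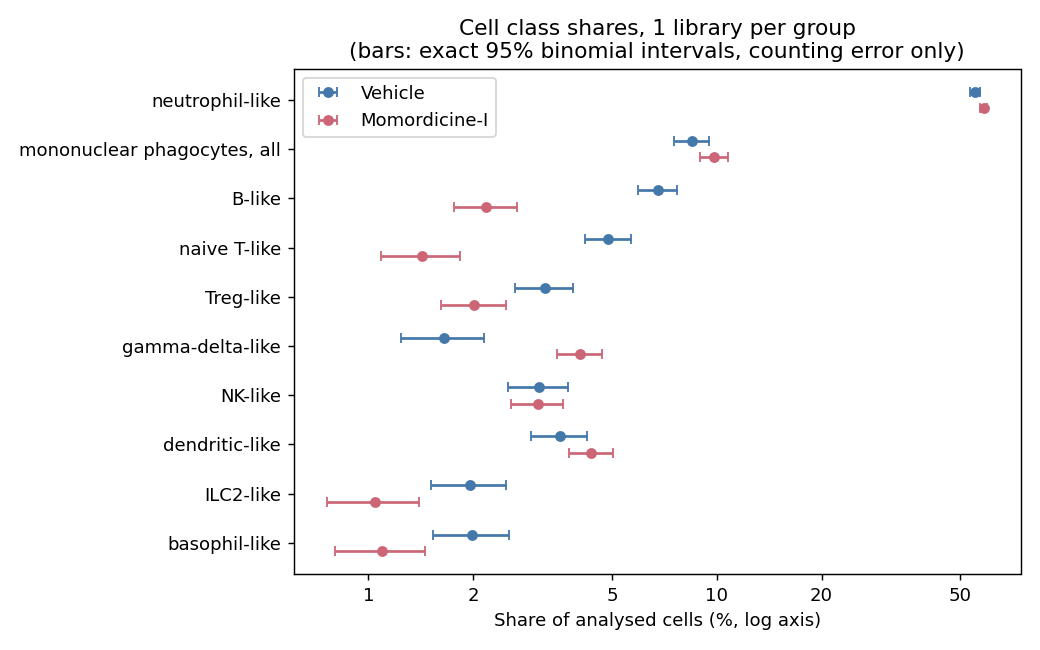
Share of analysed cells per class (percent, log axis) in the vehicle (blue) and Momordicine-I (red) libraries, with exact 95% binomial intervals. B-like cells were at 6.78% and 2.18%, gamma-delta-like cells at 1.65% and 4.06%, and NK-like cells at 3.09% and 3.06%.

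In gated mononuclear phagocytes, the stand-in for tumour macrophages (88 vehicle and 172 Momordicine-I cells), interferon-stimulated genes were lower in the Momordicine-I library. Of 19 measured members of the interferon response list, 18 were lower by at least 1.5-fold, and the list median was -1.68 on the log2 scale, below all 10000 random lists. Ifit1 (chromosome 19, 34640871 to 34650009), an antiviral RNA-binding protein, was at 118 CPM in the vehicle and 11.4 CPM in the Momordicine-I library (ratio 0.0959, 0.0614 to 0.144), with its UMIs in 13 and 8 cells. The size of these differences depended on the cells taken: the log2 ratio of Ifit1 was -3.36, -0.67 without doublet removal and -4.55 with the gate at 0.5 of its limit, and the list median was -0.83 without doublet removal and -0.85 without the gate. Ifit2, Ifit3, Ifit1bl1 and Ifi205 had ratios of 0.172, 0.135, 0.0847 and 0.174, and their log2 ratios of -2.52, -2.87, -3.51 and -2.52 were -0.80, -0.93, -1.77 and -1.32 without the gate. Cxcl10, an interferon-induced chemokine, was 85.9-fold lower, but a single cell held 63% of its vehicle UMIs, and its log2 ratio of -6.36 was -1.49 without doublet removal.

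Markers of classical (M1) and alternative (M2) activation did not separate in gated phagocytes. The M1-associated list had a median log2 ratio of -0.42, with 6 of 16 measured members lower and 2 higher, and the M2-associated list -0.33, with 6 of 16 lower and 1 higher. The M2 median turned positive in 4 of the alternatives, up to 0.06. Among M2 genes, the mannose receptor Mrc1 had a ratio of 0.560 (0.433 to 0.724; -2.98 on the log2 scale as the mean of the cells' CPM against -0.84) and the transcription factor Maf one of 0.466 (log2 -1.10, and -0.16 without doublet removal), while Retnla rested on 1 cell with 98% of its vehicle UMIs. Arg1, the arginine-degrading enzyme of suppressive myeloid cells (chromosome 10, 24915221 to 24927484), was at 314 and 446 CPM (ratio 1.42, 1.27 to 1.59), and its direction turned in 6 of 17 alternatives. Among M1 genes, Il6 and the co-stimulatory receptor Cd40 had ratios of 0.264 and 0.374, but 1 cell held 57% of the vehicle Il6 UMIs and their log2 ratios of -1.91 and -1.41 were -0.46 and -0.10 with thinned cells. Ptgs2, the inducible cyclooxygenase, had a ratio of 1.82, which turned in 1 of 17. Nos2, with 18 and 12 UMIs, had a ratio of 0.405, and it turned without its highest cell.

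Checkpoint ligands and suppressive genes went both ways in gated phagocytes, with 2 of 16 measured members higher, 3 lower and a median of -0.07, inside the range of random lists. The 2 higher were Ptgs2 and the co-stimulatory ligand Tnfsf9 (ratio 2.85, 1.55 to 5.65, level with at most 5% mitochondrial UMIs and turned in 1 of 17), and Lgals9, which encodes galectin-9, was lower (0.569). Cd274, which encodes PD-L1, was at 92.8 and 78.6 CPM (ratio 0.847, 0.675 to 1.07), Cd86 at a ratio of 0.970 and Tgfb1 at 1.11, which turned in 1, 11 and 2 of 17 alternatives. Il10 had 4 and 9 UMIs, Cd163 5 and 2, and Cxcl9 5 and 18 with the 18 in a single cell, too few to show a difference at this depth. Genes of tumour-associated macrophages had a median of 0.04 and lipid handling genes -0.18, both inside the random range. Chemokine genes went both ways, 4 of 18 higher and 8 lower, with a median of -0.24 that was 0.08 with thinned cells. Of 18 glycolysis genes none was higher by 1.5-fold and 1 was lower (median 0.13), and of 14 hypoxia genes 2 were higher, Vegfa and Bnip3 (1.63, turned in 3 of 17), and Egln3 was lower (0.648; median 0.14), with both medians below 0 without doublet removal.

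Among antigen presentation genes in gated phagocytes, 1 of 9 MHC class II genes (median -0.41, alternatives -0.82 to -0.06) and 3 of 13 MHC class I genes (median -0.23, alternatives -0.50 to -0.10) were lower by 1.5-fold and none was higher, where the median of all genes in the class was -0.09. H2-Ab1 had a ratio of 0.751 (0.720 to 0.783), and 1 cell held 17 to 20% of the vehicle UMIs of H2-Ab1, H2-Aa, H2-Eb1 and Cd74. Of 9 complement genes 5 were lower, with a median of -0.63 that was -0.10 without each gene's highest cell. The C1q genes C1qa, C1qb and C1qc had ratios of 0.639, 0.647 and 0.457, and the log2 ratios of C1qa and C1qc, -0.65 and -1.13, were -0.08 and -0.44 with the gate at 2 times its limit. Cells from the mixed cluster, which is led by C1q genes, made up 21.6% of gated vehicle and 8.14% of gated Momordicine-I phagocytes, and in monocyte-like cells C1qa was level (ratio 0.999). Among genes higher in the Momordicine-I library were the fractalkine receptor Cx3cr1 (ratio 2.89, 2.06 to 4.14, with 40% of its Momordicine-I UMIs in 1 cell and a log2 ratio of 0.20 as the mean of the cells' CPM against 1.52), the stress-response gene Nupr1 (2.22), the angiogenic factor Vegfa (1.89, 1.64 to 2.17) and the myeloid receptor Clec5a (1.95), with Gde1 (2.23), Adssl1 (2.02), Pid1 (1.90), Cited2 (1.95) and the immediate early gene Nr4a1 (1.87). Most of these shrank in an alternative: without doublet removal the log2 ratios of Clec5a, Gde1, Adssl1 and Nr4a1, 0.96, 1.15, 1.01 and 0.90, were 0.22, 0.51, 0.42 and 0.04, that of Cited2 was 0.35 without the gate against 0.96, and that of Nupr1 0.38 as the mean of the cells' CPM against 1.14. The chemokine gene Ccl4 and the lipolysis inhibitor G0s2 both had a ratio of 1.96, which turned in 4 and 6 of 17 alternatives. G0s2 is itself a neutrophil marker counted for the gate, so its value here depends on how the cells were chosen. Its log2 ratio of 0.97 was -0.39 with the gate at 2 times its limit and -0.0066 without the gate. The osteopontin gene Spp1 was lower (ratio 0.634). The lymphoid genes Rora, Tnfrsf4, Il2ra, Klrd1, Areg and Ctla2a were also lower, but came from 7 to 18 vehicle cells at 2 to 7% of their level in lymphoid classes, Areg and Ctla2a each turned in 1 of 17, and the log2 ratios of the first 4, -3.28, -3.34, -3.15 and -3.14, were -1.38, -0.59, -1.44 and -1.55 with each cell classed by its own score.

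**Figure D2:**
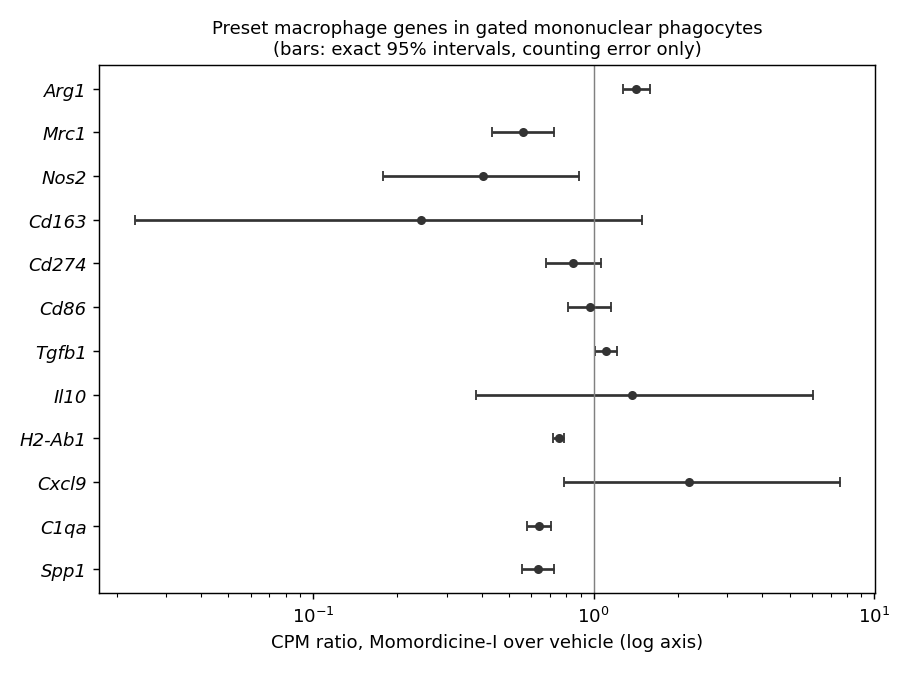
Ratio of CPM, Momordicine-I over vehicle (log axis), for the preset macrophage genes in gated phagocytes, with exact 95% intervals. Mrc1 (0.560), C1qa (0.639) and H2-Ab1 (0.751) lie below 1 and Arg1 (1.42) above it, while the interval of Cd274 holds 1.

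Monocyte-like cells (174 and 300), a set that shares 69 of the 88 and 158 of the 172 gated phagocytes and so is no separate comparison, had 14 of 19 interferon genes lower and a median of -0.89 (-1.76 with the gate on every class), among them Cmpk2 (ratio 0.263; log2 -1.92, and -3.35 with that gate), Usp18 (0.359; -1.47 and -2.44) and Irf7 (0.418). Their MHC class II median was -0.46, while the M1, M2 and checkpoint medians (-0.10, -0.09 and -0.02) lay inside the random range. Arg1 (ratio 1.05) and Tgfb1 (1.01) were level, and Cd274 had a ratio of 0.744. Cx3cr1 was higher here too (4.45, 3.36 to 5.99; log2 2.14, and 0.86 at Leiden resolution 2). In the mixed cluster (104 and 115 cells), all 7 measured MHC class II genes were lower, with a median of -2.31, although 1 cell held 30 to 39% of the vehicle UMIs of Cd74, H2-Aa, H2-Eb1 and H2-Ab1, and the median was -0.32 at Leiden resolution 2. Interferon genes had a median of -0.54 there, M1 genes -0.21 (0.28 with thinned cells) and M2 genes -0.13.

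In neutrophil-like cells (1807 and 2463), the chitinase-like gene Chil3 (chromosome 3, 106147554 to 106167564) was at 34.4 CPM in the vehicle and 536 CPM in the Momordicine-I library, a ratio of 15.6 (14.1 to 17.2; log2 3.96, and 2.44 at Leiden resolution 0.5), with UMIs in 194 and 854 cells. The collagenase Mmp8 (2.19), the acute-phase gene Saa3 (3.44) and the histone genes Hist1h4i (2.45) and H1f0 (2.52) were also higher, as was the prion protein gene Prnp (2.26). The class holds a cluster led by Retnlg, Ly6g and Mmp8 (223 and 418 cells) and another led by Saa3 (54 and 93 cells). The Mmp8 and Saa3 ratios therefore take in the mix of clusters as well as levels within them. Interferon genes were lower in the class as a whole: 10 of 18 measured members by at least 1.5-fold, with a median of -0.62, including Oasl1 (ratio 0.475, 0.431 to 0.524), Ifi27l2a (0.516), Zbp1 (0.532) and Rtp4 (0.572). A neutrophil-like cluster is led by interferon genes (Ifit1, Rsad2, Ifit3), so the class value takes in the mix of clusters as well as levels within them. Outside that cluster 11 of 18 members were lower, with a median of -0.69, while inside it none passed 1.5-fold and the median was 0.18, values looked at after the class result was seen in clusters drawn with these genes. Slfn4, another interferon-induced gene, Rnf213, and the chemotactic factor Prok2 had ratios of 0.510, 0.509 and 0.514, and Spp1 was at 299 and 150 CPM. Chemokine genes had a median of -0.29 and nuclear-encoded oxidative phosphorylation genes 0.29 (alternatives 0.13 to 0.30), where the median of all genes in the class was 0.16. Medians were -0.10 for checkpoint genes, -0.15 for late or tumour-associated neutrophil genes and -0.03 for genes of mature blood neutrophils.

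The list of neutrophil granule and early-stage genes had a median of 0.87, with 7 of 12 measured members higher in the class. Camp, Ngp and Ltf, granule proteins made in the marrow, had ratios of 14.3, 3.70 and 2.60, and 1 cell held 56%, 37% and 29% of their Momordicine-I UMIs. An unnamed cluster led by Ngp and Camp, with 13 vehicle and 2 Momordicine-I cells, lay outside the class. With it included, the list median was -0.08, Camp, Ngp and Ltf had ratios of 0.145, 0.236 and 0.385, and Chil3 had a ratio of 5.35 (5.04 to 5.68). Il1b had a ratio of 1.18, Cxcr2 1.14, Siglecf, a marker of tumour-associated neutrophils, 1.62, and Cd274 0.802. S100a8, S100a9 and Ptgs2 lay between 0.939 and 0.988, and each changed sign in 1 to 3 of 14 alternatives.

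**Figure D3:**
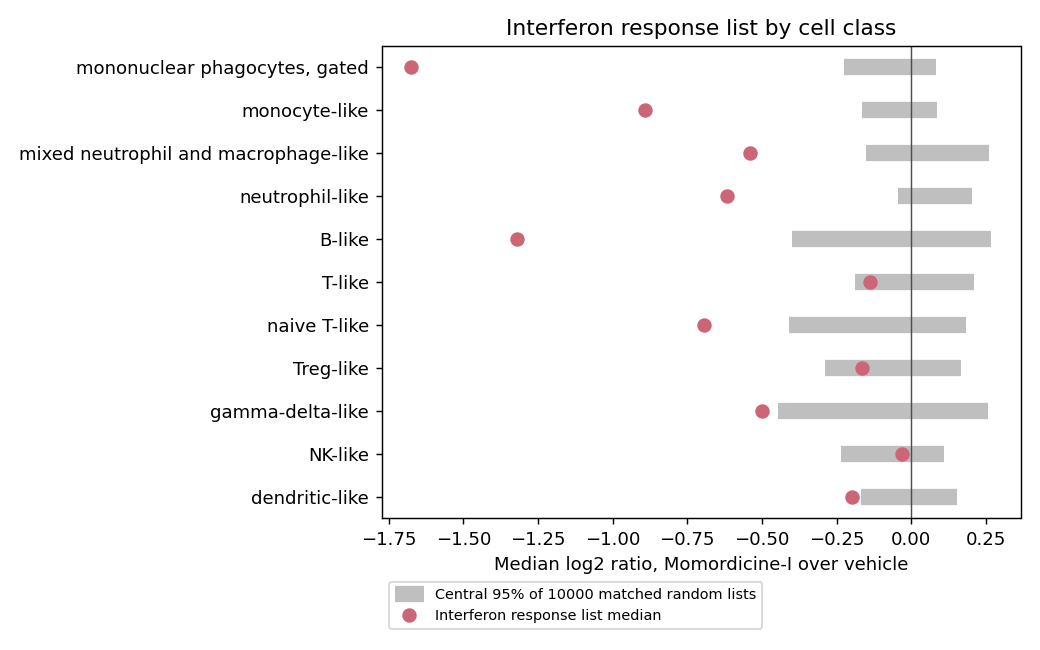
Median log2 ratio of the interferon response list per class (points), Momordicine-I over vehicle, beside the central 95% of matched random lists (grey). The median was -1.68 in gated phagocytes, -1.32 in B-like, -0.62 in neutrophil-like and -0.03 in NK-like cells.

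In B-like cells (222 and 92), interferon-stimulated genes were again lower, with 11 of 13 measured members lower and a median of -1.32, below all random lists. Slfn5 (chromosome 11, 82951349 to 82964840), an interferon-induced gene, was 26.8-fold lower (7.31 to 223; log2 -4.43, and -2.31 as the mean of the cells' CPM), with UMIs in 55 vehicle and 2 Momordicine-I cells. Ifi27l2a had a ratio of 0.312 (0.248 to 0.389), and Ifi213 and Ifi206 had ratios of 0.148 and 0.224. Bcl11a, a transcription factor of B cell development, was at 281 and 115 CPM (ratio 0.408, 0.301 to 0.542). Ikzf2 and Ecm1 (turned in 4 of 13 alternatives) were also lower, but 1 cell held 60% and 85% of their vehicle UMIs, and Ikzf2 was level without doublet removal.

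B cell activation genes went both ways: 3 of 13 measured members were higher and 2 lower, and the median of 0.33 was -0.09 without doublet removal. Higher by at least 1.5-fold were the homing receptor Ccr7 (ratio 1.67), Myc (1.77, with 24% of its Momordicine-I UMIs in 1 cell) and the adhesion receptor Cd44 (1.66, log2 0.73, which was -0.31 without doublet removal), while the early activation markers Cd69 (1.49, 1.30 to 1.71) and Cd83 (1.26) did not reach that limit. Genes higher by rank included Ahnak (3.23), Tagln2 (3.05) and Myadm (4.42), Emb (2.41), Kdm5b (2.94) and Gimap9 (2.33), with S100a6 (2.91) and Pim1 (2.05), which both turned without doublet removal. The log2 ratio of Myadm, 2.14, was 1.30 without doublet removal, and that of Kdm5b, 1.56, was 3.35 with thinned cells. The splicing factor gene Snrpb2 was lower (0.183; log2 -2.36, and -1.47 without doublet removal). MHC class II genes had a median of -0.40 and their regulator Ciita a ratio of 0.572, and MHC class I genes a median of -0.37. Identity genes had a median of -0.20: Cd79a had a ratio of 0.851, Ms4a1 0.905, Ighm 1.11 and Ighd 0.878. For regulatory B cell genes the median was 0.19, inside the random range, with Cd274 at 1.30 (0.920 to 1.82, turned in 1 of 13) and Tgfb1 at 1.16 (0.898 to 1.49). Il10 had 1 UMI in each library. Plasma cell genes had a median of -0.14, and genes of atypical B cells 0.38, which was -0.32 without each gene's highest cell.

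**Figure D4:**
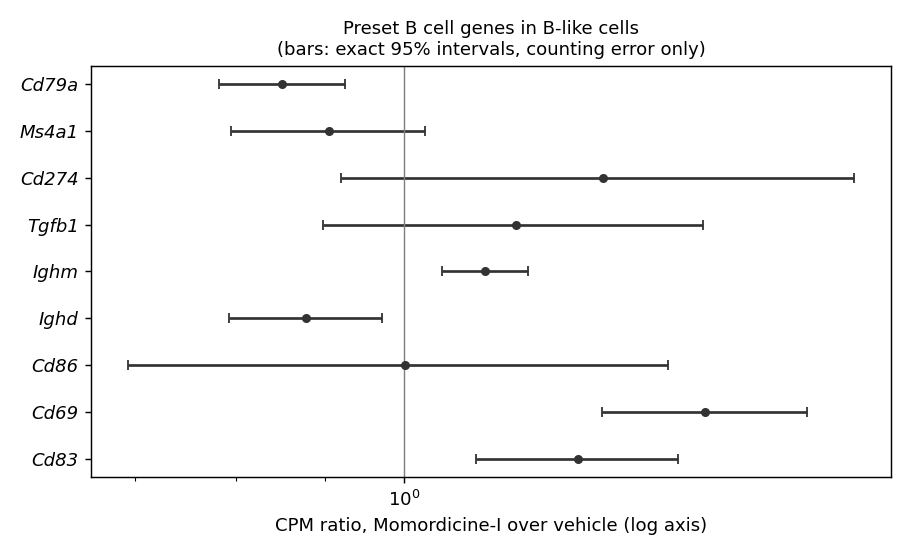
Ratio of CPM, Momordicine-I over vehicle (log axis), for the preset genes in B-like cells, with exact 95% intervals. Il10, with 1 UMI in each library, is left out, Cd69 (1.49) and Cd83 (1.26) lie above 1, and Cd79a (0.851) lies below it.

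T-like cells (319 and 316) comprised the naive T-like, Treg-like and gamma-delta-like clusters in different proportions, so the class values take in the mix of clusters as well as levels within them. Genes that lead the gamma-delta-like cluster were higher, such as Il17a (ratio 4.46), Tmem176a (4.51) and Blk (4.18), and naive genes had a median of -1.05, including Lef1 (0.428). Cd8a was at 40.4 and 4.82 CPM, Cd4 had a ratio of 0.503, Foxp3 0.617, Tcf7 0.489, Ctla4 0.755, Lag3 0.292 (log2 -3.00 for Cd8a and -1.75 for Lag3, which were -0.47 and -0.23 with each cell classed by its own score), Gzmb 0.755, Havcr2 0.916 (0.669 to 1.25, turned in 5 of 14) and Pdcd1, which encodes PD-1, 2.21. Tigit had 10 and 7 UMIs, and Ifng 13 and 26, of which 1 cell held 77% in the Momordicine-I library. List medians in the class were -0.40 for exhaustion, -0.49 for cytotoxicity (0.06 at Leiden resolution 2), -0.16 for activation, -0.40 for Treg and -0.14 for interferon genes (0.21 with at most 5% mitochondrial UMIs). Within gamma-delta-like cells (54 and 171) Pdcd1 was level (ratio 0.985, 0.810 to 1.20) and the activation receptor Tnfrsf9 lower (0.401; log2 -1.32, and -0.67 at Leiden resolution 0.5), with medians of -0.27 for activation, -0.03 for exhaustion and -0.50 for interferon genes (0.22 with thinned cells). Within naive T-like cells (160 and 60) interferon genes had a median of -0.70, naive genes -0.23 and activation genes 0.12 (-0.17 without doublet removal), the last 2 of which were -1.03 and 1.10 with each library clustered on its own. Within Treg-like cells (105 and 85) the activation list had a median of -0.28, the exhaustion list -0.36 (0.08 with no mitochondrial limit), the interferon list -0.17 (0.58 with at most 5% mitochondrial UMIs) and the Treg list -0.34, with Il2ra at a ratio of 0.646, Ctla4 at 0.781, Lag3 at 0.356 (log2 -1.46, and -0.41 at Leiden resolution 2) and Foxp3 at 0.798, the last of which was 0.01 on the log2 scale where each library was clustered on its own. Csta2, Stfa2 and Cstdc5, granulocyte genes, were lower in Treg-like cells, where 1 cell held 88 to 99% of vehicle UMIs, and each was higher with no mitochondrial limit. Neutrophil markers made up 1.15% of Treg-like UMIs in the vehicle and 2.22% in the Momordicine-I library, and T cell markers 0.331% and 0.257%. Chil3, Mmp8, Slpi and Lcn2 led the higher genes there, and each turned in 1 to 3 of 14 alternatives. More neutrophil RNA lowers the CPM of other genes, and its part in the lower Treg-like values was not tested.

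In NK-like cells the interferon median was inside the random range (-0.03, and -0.46 with thinned cells). Exhaustion genes had a median of 0.09 and cytotoxicity genes 0.02, both of which turned in some alternatives, with granzyme B (Gzmb) at a ratio of 0.616 and Ifng at 0.580. Pdcd1 was higher (3.44, 2.65 to 4.51; log2 1.77, and 0.83 with thinned cells), in 12 and 34 cells. Immediate early and dissociation-associated genes had a median of -0.28, including Hspa1b (0.525) and Fos (0.608). In dendritic-like cells (116 and 184) MHC class II genes had a median of 0.18, which was -0.08 with at most 5% mitochondrial UMIs, and chemokine genes -0.35, which was 0.07 where the gate was put on every class. Their interferon median was -0.20, which was 0.47 with that gate, and their checkpoint median 0.07, which was -0.12 with each cell classed by its own score. Gzmb, at 4% of its NK-like level, was lower in dendritic-like cells (log2 -2.61, and -0.50 with each cell classed by its own score), and Gzma and Gzmc were higher, with 53 to 86% of their UMIs in 1 cell and the other direction in 3 and 4 of 14 alternatives.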

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

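The tests on composition and the free RNA tests were chosen after those results were seen, and the rules for reading the lymphoid tissue test and the interferon free RNA test were made stricter after their values were known, while the tests on few cells, depth and early-stage cells were written down before their values were computed.

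B-like and naive T-like shares were both lower in the Momordicine-I library. Dilution by more neutrophil-like cells would have lowered NK-like cells as well, but their ratio was 0.991 (0.758 to 1.30). Lymph node tissue or blood in the vehicle suspension would bring both cell types together, but the number of B-like cells per naive T-like cell, 1.39 and 1.53 (ratio 1.11, 0.741 to 1.66), follows from the 2 share ratios and decides nothing. Igkc outside B-like cells was lower by more than the B-like share (ratio 0.0260 in neutrophil-like cells). Plasma cells or blood in the vehicle suspension may be its source, which was not tested, and no cluster was named plasma-like in either library. An effect of Momordicine-I on both cell types stays open as well, and with 1 library per group the 2 could not be told apart.

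Interferon genes were lower in gated phagocytes, neutrophil-like and B-like cells. Without the 5% of cells highest in these genes, the medians were -1.50, -0.99 and -1.39, so those 5% alone did not carry the direction. A larger subset is not excluded: the neutrophil-like cluster led by interferon genes held 286 vehicle and 208 Momordicine-I cells. These are more than 5% of the class in each library, and an equal cut can take a larger part of the smaller group. Outside that cluster the median was -0.69. With the cells under 2000 UMIs left out (10 and 17 gated phagocytes, 148 and 188 neutrophil-like and 6 and 3 B-like cells) and the others thinned to that number, the class medians were -1.28, -0.68 and -1.53. Depth thus did not carry the direction among the cells kept. Free interferon-gene RNA in the vehicle droplets would have lowered NK-like cells too. The NK-like median was -0.03, but its interval over the list members (-0.47 to 0.15) and its value of -0.46 with thinned cells leave this explanation undecided. Other lymphoid classes were not part of that test. Their medians were -0.70 in naive T-like (alternatives -1.10 to -0.39), -0.50 in gamma-delta-like and -0.17 in Treg-like cells. The gamma-delta-like and Treg-like medians took another sign in some alternatives. An effect of the treatment is left undecided as well by 1 library per group.

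Chil3, Camp, Ngp and Ltf were higher in neutrophil-like cells. Chil3 UMIs per neutrophil-like cell were 11.4 times (9.71 to 13.5) those per lymphocyte in the Momordicine-I library, so free monocyte RNA alone did not account for them. Between libraries, Chil3 UMIs per lymphocyte were higher as well, at 0.0467 in the vehicle and 0.281 in the Momordicine-I library. The Chil3 ratio in T-like cells was 8.33, which turned in 2 of 14 alternatives. A part of free RNA in the neutrophil-like ratio thus stays open. Without the 5% of cells of the class highest in early-stage genes the Chil3 ratio was 14.2 (12.8 to 15.7), while the joint ratio of Camp, Ngp and Ltf was 1.21 (1.05 to 1.39), so the cells removed made most of the latter difference. They were picked by a list that holds these genes, so the cut shows how concentrated the UMIs were and not the stage of the cells. The class had been formed without a cluster led by Ngp and Camp (13 vehicle and 2 Momordicine-I cells), and with it Chil3 had a ratio of 5.35 (5.04 to 5.68) and Camp, Ngp and Ltf had 0.145, 0.236 and 0.385, so the size of the first and the direction of the others depended on where that cluster was put. For Chil3, 1 library per group does not separate an effect of the treatment from other differences between the pooled tumours.

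Tumour-like cells, outside every comparison, made up 1.33% of the CD45-sorted Momordicine-I library and 0.825% of the vehicle library, and stood out because the sort should exclude them. The separate low-UMI tumour-like cluster held a further 5.12% and 3.24%. An unnamed cluster led by the osteoclast genes Ctsk, Acp5 and Atp6v0d2, also outside every comparison, held 0.545% of Momordicine-I and 0.0611% of vehicle cells (23 and 2). The gamma-delta-like share ratio of 2.46 went opposite to the naive T-like one, a difference between T cell groups that was not tested.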

How the results depend on the processing

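The 14 planned and 5 added alternatives gave 6851 values for 493 results, of which 368 values in 163 results had the other direction. For 145 of them, in 87 results, the interval of the value as reported lay wholly on 1 side of no difference. Of the 13 share ratios that were given alternatives, 11 kept their direction, and the dendritic-like (0.997 to 1.46) and NK-like ones (0.955 to 1.14) had ranges that span 1. The B-like ratio ranged from 0.279 to 0.329, naive T-like from 0.220 to 0.514 and gamma-delta-like from 1.43 to 2.95. Of named genes, 46 of 71 kept their direction in every alternative in gated phagocytes, 33 of 41 in neutrophil-like, 44 of 55 in B-like, 36 of 47 in T-like, 20 of 35 in Treg-like and 12 of 24 in dendritic-like cells. The interferon medians stayed negative, from -2.13 to -0.83 in gated phagocytes, -0.77 to -0.60 in neutrophil-like and -1.56 to -1.25 in B-like cells. Of 60 described list and class pairs, 30 took another sign at least once, 86 medians in all, among them not only small ones: the neutrophil granule list at 0.87 (to -0.09), T-like cytotoxicity at -0.49 (to 0.06) and gamma-delta-like interferon genes at -0.50 (to 0.22). Depth limits genes under 20 UMIs, and classes with fewer cells, such as the 92 B-like cells of the Momordicine-I library, have wide intervals. Some alternatives gave no value for classes they did not keep apart or leave unchanged. The 145 values, and those that moved beyond their interval for the main shares and lists, follow as log2 ratios unless named as share ratios. The cause was not tested, except that putting the early-stage cluster back gave a granule list median of -0.084, near the value at Leiden resolution 0.5.

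With at most 5% mitochondrial UMIs, the values were in gated phagocytes Ccl4 -0.41, G0s2 -0.21, Arg1 -0.051, Ccl17 0.80, and in monocyte-like Ccl17 0.62, and in Treg-like Stfa2 1.00, and in T-like Stfa2 0.67, and in dendritic-like Cd74 -0.021.

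With no mitochondrial limit, the values were in gated phagocytes G0s2 -0.40, Arg1 -0.10, Ccl12 0.33, and in Treg-like Chil3 -0.23, Csta2 0.93, Stfa2 3.29, Stfa1 0.79, Cstdc5 3.29, and in T-like Csta2 0.41, Stfa2 3.05, Cstdc5 2.40, Stfa1 0.72, Gzma 1.21, Klrd1 0.028, and in dendritic-like Gzma -3.76, Gzmc -3.09, Arg1 0.021.

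With at least 500 genes per cell, the values were in gamma-delta-like Cxcl10 -1.49, and in Treg-like Stfa1 2.63, and in T-like Stfa1 2.01.

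Without doublet removal, the values were in gated phagocytes the Glycolysis list -0.029, Ccl4 -0.51, G0s2 -0.11, Bnip3 -0.031, P4ha1 -0.013, and in B-like S100a6 -0.032, Pim1 -0.032, Cd44 -0.31, and in naive T-like Icos -0.22, and in dendritic-like Cxcl3 0.053.

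At Leiden resolution 0.5, the values were in neutrophil-like the Neutrophil granules and early stages list -0.092, Ngp -2.10, Ltf -1.38, Ptgs2 0.016, Camp -2.80, Cd177 -0.17, and in gamma-delta-like share ratio 1.43.

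At Leiden resolution 2, the values were in gated phagocytes the MHC class II presentation list -0.82, and in monocyte-like Ccr7 -1.71, and in T-like Gzma 1.32, Klrd1 0.11, and in dendritic-like Gzma -3.61, Gzmc -3.75, Arg1 0.079.

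With each library clustered alone, the values were in gated phagocytes Ccl17 5.90, and in B-like Ecm1 0.78, and in naive T-like share ratio 0.514, Nr4a1 0.73, and in Treg-like Chil3 -2.24, Slpi -1.68, Lcn2 -0.41, Foxp3 0.014, and in T-like Chil3 -0.94, and in NK-like H2-Ab1 2.44, H2-Eb1 2.28, H2-Aa 2.40, Cd74 2.54, and in dendritic-like the MHC class II presentation list 0.29, Gzma -3.43, Gzmc -3.81, Ccl9 -0.11, Rsad2 0.17, Cxcl10 0.43.

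With each cell classed by its own score, the values were in gated phagocytes the Glycolysis list -0.075, Ccl4 -0.57, Ptgs2 -0.25, G0s2 -0.042, Areg 0.52, Ctla2a 0.47, Arg1 -0.15, Tgfb1 -0.11, Tnfsf9 -0.11, Lpl 0.016, Fabp4 1.33, Bnip3 -0.22, P4ha1 -0.32, and in monocyte-like share ratio 1.86, Csta2 -1.37, Ccl17 0.43, Mrc1 0.19, Ccr7 -1.88, Irf4 0.044, and in neutrophil-like Ptgs2 0.011, and in B-like Ecm1 1.06, and in naive T-like share ratio 0.400, Cdkn1a -0.051, Cxcl2 -0.70, Cd8a 0.22, Nr4a1 0.0082, and in Treg-like Chil3 -0.87, and in T-like Chil3 -0.63, Ifng -0.43, and in NK-like Cxcl10 -0.038, and in dendritic-like Gzmc -0.28, Ccl9 -0.12, Lyz2 -0.12, Cd80 -0.12, Ifi44 -0.25.

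As the mean of the cells' CPM, the values were in gated phagocytes Arg1 -0.0028, Tgfb1 -0.030, Cmpk2 0.073, and in neutrophil-like S100a8 0.015, S100a9 0.068, Ptgs2 0.015, and in Treg-like Rtp4 -0.12, Il10 0.029, and in T-like Cd40lg -0.10.

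With cells thinned to 2000 UMIs and those with fewer left out, the values were in gated phagocytes Trem2 -0.13, H2-DMb2 0.15, Psmb9 0.032, Gpi1 -0.37, and in monocyte-like Ccr7 -0.76, Il23a -0.15, and in neutrophil-like S100a9 0.044, and in B-like Ecm1 0.65, and in Treg-like Ikzf4 0.25, and in NK-like Klrg1 0.36, and in dendritic-like Lgals9 0.26.

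With the gate at 2 times its limit, the values were in gated phagocytes G0s2 -0.39, Arg1 -0.13, Ccl12 0.025.

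Without the gate, the values were in gated phagocytes share ratio 1.16, Ccl4 -0.65, G0s2 -0.0066, Arg1 -0.0042, Bnip3 -0.0015.

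With the gate on every class, the values were in all mononuclear phagocytes share ratio 1.52, and in monocyte-like share ratio 1.78, the Interferon response list -1.76, Ccr7 -1.32, and in naive T-like Cxcl2 -0.21, and in Treg-like Mmp8 -0.96, Slpi -1.13, Stfa2 0.62, Stfa1 2.21, and in T-like Stfa2 0.23, Stfa1 1.33, and in NK-like S100a8 -0.12, and in dendritic-like Rsad2 1.39, Cxcl10 1.16.

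Without each gene's highest cell, the values were in mixed-cluster cells Cxcl10 0.28, and in gated phagocytes Nos2 0.36, and in monocyte-like Ccr7 -0.75, and in B-like Ecm1 0.38, and in naive T-like Cxcl2 -0.22, and in gamma-delta-like Il17f 2.22, and in T-like Ifng -0.47.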

Other observations

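Immunoglobulin RNA outside B-like cells differed between the libraries, a result looked at after its values were seen. Whether the RNA was made in these cells or was free in the droplets was not tested, so the CPM below are what the droplets of each class held. Igkc, the kappa light chain constant gene, was level in B-like cells (ratio 1.06, 1.00 to 1.11), but in neutrophil-like cells it was at 112 CPM in the vehicle and 2.92 CPM in the Momordicine-I library (ratio 0.0260, 0.0187 to 0.0352). The ratio was 0.0150 in monocyte-like, 0.0283 in NK-like, 0.0336 in T-like and 0.0484 in dendritic-like cells, and gated phagocytes had 88 and 0 UMIs. Ighm ratios outside B-like cells were nearer to 1, such as 0.199 in neutrophil-like and 0.618 in NK-like cells.

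A mast-like cluster held 1 vehicle and 14 Momordicine-I cells, 0.0306% and 0.332%, so it belongs almost wholly to 1 library.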
